A study of Mus musculus with 9 samples.

How the data were processed

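Single cells of dissociated mouse aortas were profiled in 9 libraries. The labels give 8-week-old male mice in 3 groups of n = 3, named here WT (Tet2flox/flox, vehicle), WT_VD (Tet2flox/flox, high-dose cholecalciferol) and KO_VD (Tet2SMC-KO, high-dose cholecalciferol), with replicate numbers 1 to 3 in each. A Tet2SMC-KO group with vehicle was not analysed here, so the genotype was compared under vitamin D3 only. The labels do not state that each library came from a separate animal, so p-values of genes and class shares measure the spread between samples. The p-values of gene lists from camera and of nearness to Tet2 from a Fisher test set genes against other genes. They do not measure that spread by themselves. Per the labels the aortas were dissociated with collagenases and hyaluronidase, and libraries were made with the 10x Genomics 3′ kit version 3.1.

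The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 5.0.0 (per the file headers) on the mouse build mm10 (per the labels), with no normalization. The annotation release and the rule for calling cells are not given in the sources used here, and the lowest barcode held 500 to 502 UMIs in every library. Barcodes per library numbered 8652, 7769 and 9617 in WT 1 to 3, 9786, 13058 and 7783 in WT_VD 1 to 3, and 8238, 7095 and 8066 in KO_VD 1 to 3. Median UMIs per barcode were 12587.5, 12473 and 11372 in WT, 13165.5, 2485 and 11023 in WT_VD, and 12425.5, 9655 and 8460 in KO_VD. The 32285 genes were placed with GENCODE release M21 on the same build (99.85% found), and 78 duplicated symbols were kept apart by gene ID.

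Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublet scores followed the Scrublet method per library. Its automatic threshold marked 0 cells in 6 libraries and at most 1.17% of cells in any, and was not workable, so the highest scores were removed at a rate of 0.8% per 1000 barcodes, a choice made after the data were seen. Kept cells numbered 6962, 6505 and 7659 in WT, 7929, 10669 and 6513 in WT_VD, and 7074, 6154 and 6498 in KO_VD. Counts were log-normalised, and 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 gave 35 clusters (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Python 3.11.15). Clusters were named from markers of 24 classes. A marker counted when at least 0.25 of cells held it and its mean reached 0.25 of the highest cluster mean. A class needed 0.5 of its markers, and at least 3. A cluster stayed unnamed when a second class reached 0.75 of the share of the first, when its top 10 genes held more markers of another class, when it had few UMIs and no marker among its top 10 genes, or when over 0.5 of its cells were removed as doublets. The markers were fixed beforehand, and these thresholds were set with the data at hand.

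UMIs were summed per library and class for SMC, fibroblasts, endothelial cells and macrophages, since cells of a library are not replicates. A library with fewer than 20 cells of a class was left out, which removed WT 2 from the macrophages (17 cells). Sums over the SMC ran from 7555087 UMIs in KO_VD 2 to 74307897 in WT 3. Each class was fitted over all its libraries in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p of genes and of the difference between classes come from edgeR. CPM are counts scaled to a common total with the TMM factors, given as mean ± SD over libraries, except the values of Tet2 per library, which are UMIs scaled to the total of each sum alone. Values of log2 are fitted log2 ratios, with ± SE. The difference between SMC and fibroblasts was tested as the class by group term with library as a block.

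The 39 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Members were counted over all genes and adjusted over the list alone. Class shares were compared by exact two-sided permutation over 20 assignments, where 3 against 3 cannot go below 0.1. Groups, comparisons, tests, class markers, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Named were the 8 largest rises and 8 largest falls in each SMC comparison (4 and 4 in other classes) with adjusted p under 0.05, a mean of at least 20 CPM and no overlap. Added were up to 4 members with the smallest p of each list called (2 in other classes), Tet2, and in SMC Myh11, Acta2, Runx2, Sox9, Spp1, Alpl and Cyp24a1. Gene models without a name and mitochondrial, ribosomal, haemoglobin and immunoglobulin genes were not taken by size. All genes taken by size are printed. Of the list members the text prints a part, chosen after values were seen, while the counts of each list cover every member. Some named list members are not reported here.

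The alternatives were DESeq2 1.42.0, RLE size factors, no filter or a stricter filter on low counts (10 CPM in 3 libraries), only the libraries compared, a replicate block, cells with at least 1000 genes and at most 10% mitochondrial UMIs, doublets kept, Leiden at resolution 2, equal cell numbers (284 SMC, 1505 fibroblasts, 82 endothelial cells and 26 macrophages per library) and leaving out each library. Alternatives added after the data were seen were subtraction of free RNA, removal of cells with Xist, replicates 2 and 3 alone, SMC cluster 7 alone and shares of named cells alone. Free RNA was taken as the profile of all kept cells of a library, scaled by genes that the class should lack, at up to 8.87% of a sum. In SMC and fibroblasts these genes included Cd74 and Tyrobp. The labels give the groups the same replicate numbers. Whether the numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. Every correlation was over 0.1 (lowest 0.11) for vitamin D3 in SMC and fibroblasts and for KO_VD against WT in SMC. The same held for the genotype in fibroblasts, endothelial cells and macrophages. There the numbers were taken as pairs, and calls that a replicate block changed are given. The main fits of each class hold the groups alone, without that block, so their adjusted p take no account of pairing. Except for the genotype in fibroblasts, some of these libraries correlated better with another number (SMC, vitamin D3, replicate 2: 0.163 and 0.404). The correlations do not settle that the numbers pair the libraries. Replicate 1 stood apart: against replicates 2 and 3, 234 genes differed in SMC and 1228 in fibroblasts with group in the model, so values with replicates 2 and 3 alone are given, while replicate 1 holds 1 library per group, too few for its own value.

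The fits were tested on simulated data with 200 genes changed. Of genes changed 2-fold and 4-fold, 70% and 91% were recovered for vitamin D3 in SMC, 56% and 86% for the genotype in SMC, 44% and 72% and 36% and 87% in fibroblasts, 14% and 61% and 27% and 75% in endothelial cells, and 0% and 25% and 4% and 51% in macrophages. Unchanged genes made up 8.52% of the genes called for vitamin D3 in SMC and up to 8.93%, for the genotype in endothelial cells, above the threshold of 5%. Genes shared by comparisons that use the same libraries were set against 20 simulations of groups without differences. Plots were drawn with matplotlib 3.10.9.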

Results

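The labels describe 3 groups of male mice, from which dissociated aortic cells were sequenced with n = 3 libraries per group: Tet2flox/flox with vehicle (WT), Tet2flox/flox with high-dose vitamin D3 (WT_VD) and Tet2SMC-KO with vitamin D3 (KO_VD). To ask how the make-up of the wall differed, clusters were named from fixed markers and the share of each class was compared per library. Vitamin D3 treatment went with a loss of cells carrying contractile markers and a gain of myeloid cells. SMC-like cells (SMC from here on) made up 62.1 ± 2.27% of the cells in WT and 25.8 ± 10.7% in WT_VD (mean ± SD), a share 2.54-fold lower. Folds of shares were taken between means of log2 shares, so they differ from the ratio of the means given. Macrophage-like cells made up 0.349 ± 0.0923% and 9.34 ± 9.48%, and neutrophil-like cells 0.182 ± 0.241% and 4.68 ± 4.21%, shares 19.7-fold and 39.5-fold higher. Without WT_VD 3, which held 20.3% macrophages and 9.49% neutrophils, they stood higher by log2 3.50 and 4.60, and over all single libraries left out by 3.50 to 4.74 and 4.41 to 6.48. Endothelial-like cells were 1.73-fold higher. Pericyte-like cells averaged 0.0509% and 0.201%, from 1, 9 and 0 cells in WT 1 to 3, while the fibroblast-like share was 27.4 ± 0.608% and 26.2 ± 8.06% (log2 -0.11, exact two-sided permutation p = 0.7, log2 0.11 without WT_VD 2). In each of these classes except the fibroblasts the 3 libraries of one group lay wholly apart from those of the other (exact p = 0.1, the smallest value that 3 against 3 can give). At resolution 2 the endothelial shares overlapped (exact p = 0.2) and no pericyte class was named. On cell counts edgeR called macrophages (log2 4.73, adjusted p = 0.00341) and neutrophils (log2 4.67, adjusted p = 0.0156). Counted against fibroblasts, SMC numbered 2.27 ± 0.122 per fibroblast in WT and 0.963 ± 0.103 in WT_VD (log2 -1.24, exact p = 0.1). In WT_VD 2, a library with a median of 2485 UMIs per barcode, 55.0% of cells stayed unnamed, and without it the SMC share differed by log2 -1.09. The plot of class shares shows every library.

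Among vitamin D3 treated animals the Tet2SMC-KO libraries held still fewer SMC and more leukocytes. The SMC share was 9.59 ± 6.59% in KO_VD, 2.96-fold lower than in WT_VD, but the libraries of the groups overlapped (exact p = 0.2), with 17.1% in KO_VD 1 and 17.0% in WT_VD 2. They did not overlap with the stricter cell filter, with doublets kept, at resolution 2 or among named cells only (exact p = 0.1 in each). Per fibroblast, SMC numbered 0.420 ± 0.334 in KO_VD without overlap (log2 -1.48, exact p = 0.1). Neutrophil-like cells reached 13.7 ± 2.51% (3.79-fold higher, log2 1.37 to 2.63 with single libraries left out), B cell-like cells 1.37 ± 0.401% against 0.288 ± 0.205% (5.45-fold) and endothelial-like cells 4.13 ± 0.454% against 2.61 ± 0.610% (1.61-fold), each without overlap (exact p = 0.1). The endothelial shares overlapped at resolution 2 (exact p = 0.7) and among named cells only (exact p = 0.3). Macrophage-like cells reached 24.8 ± 7.49%, with overlap (exact p = 0.2, and 0.1 in the same 4 settings as for SMC). The fibroblast share was 24.0 ± 2.48% (log2 -0.09, exact p = 0.8, log2 0.14 without WT_VD 1). At resolution 2 the fibroblast share was lower in KO_VD than in WT_VD, without overlap. Fibroblasts held unlike numbers of UMIs, with medians per cell of 6894 to 9186 in the WT libraries, 11080 to 19840 in WT_VD and 22540 to 41508 in KO_VD. The shares count cells that passed through dissociation and cell calling. In KO_VD 1 to 3 an Xist UMI, flagged below, was held by 9.61, 13.4 and 12.6% of SMC. The same held for 41.5, 12.5 and 33.6% of macrophages. Shares without these cells were not computed.

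**Figure D1:**
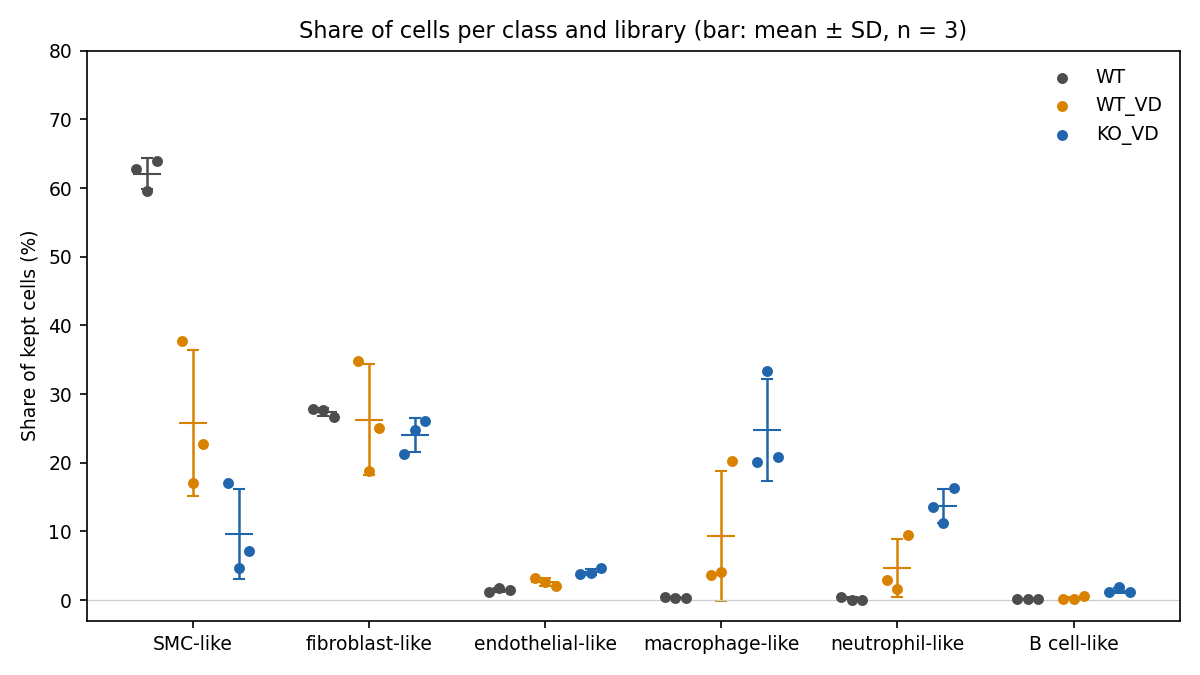
Share of kept cells (%) in 6 classes for each library (points), with mean ± SD (bars), in WT, WT_VD and KO_VD. The SMC share averages 62.1% in WT and 25.8% in WT_VD.

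Tet2, which codes for a 5-methylcytosine dioxygenase and is the gene named by the knockout label, was read in every library (chromosome 3, 133463679 to 133545139). In SMC it gave 24.4, 28.6 and 27.8 CPM in WT 1 to 3, 26.2, 30.1 and 31.0 CPM in WT_VD 1 to 3, and 32.5, 24.8 and 28.0 CPM in KO_VD 1 to 3. Between KO_VD and WT_VD the difference was log2 -0.02 ± 0.11, adjusted p = 0.948 in SMC and log2 0.03 ± 0.21, adjusted p = 0.950 in fibroblasts. It was log2 0.48 ± 0.18, adjusted p = 0.476 in endothelial cells and log2 -0.24 ± 0.20, adjusted p = 0.959 in macrophages. Between WT_VD and WT it was log2 0.02 ± 0.11, adjusted p = 0.942 in SMC, log2 0.35 ± 0.19, adjusted p = 0.342 in endothelial cells and log2 0.42 ± 0.25, adjusted p = 0.431 in macrophages. In fibroblasts it was log2 0.59 ± 0.21, adjusted p = 0.0954, and adjusted p = 0.0311 with a replicate block (range over the alternatives 0.0159 to 0.247). The tags lie near the 3′ ends of transcripts and the labels do not say which part of the gene was deleted, so these values do not check the deletion.

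To ask what vitamin D3 treatment changed within SMC, UMIs were summed per library and compared with edgeR. Spp1, coding for the mineral-binding matrix protein osteopontin, rose from 1.26 ± 0.987 to 889 ± 691 CPM (log2 9.44 ± 1.04, adjusted p = 0.00200), a 694-fold rise, with log2 8.55 (without WT_VD 3) to 10.03 over the alternatives. Vcam1, the vascular adhesion molecule, rose from 20.7 ± 2.71 to 459 ± 26.2 CPM (log2 4.47 ± 0.36, adjusted p = 0.000857), and Timp1, a metalloproteinase inhibitor, from 25.5 ± 8.53 to 504 ± 105 CPM (log2 4.31 ± 0.46, adjusted p = 0.00195). Lcn2, the siderophore-binding lipocalin, rose 192-fold (log2 7.58 ± 1.08, adjusted p = 0.00474), Esm1, a proteoglycan of activated endothelium, 53.9-fold (log2 5.75 ± 0.50, adjusted p = 0.00103) and Procr, the protein C receptor, 34.6-fold (log2 5.11 ± 0.33, adjusted p = 0.000744). The neutrophil chemokine Cxcl2 rose 60.7-fold (log2 5.92 ± 0.68, adjusted p = 0.00224), and the monocyte chemokine Ccl2 37.4-fold (log2 5.22 ± 0.78, adjusted p = 0.00606), though Ccl2 gave log2 3.12 (adjusted p = 0.0846, range over the alternatives 1.57e-08 to 0.0978) at resolution 2. Of 17059 genes tested 1282 passed, 1053 higher and 229 lower (1183 with replicates 2 and 3 alone). The groups did not overlap for 36.5% of all genes, where chance gives 10% for 3 against 3. Without WT 1, WT 2, WT 3, WT_VD 2 or WT_VD 3 the number was 628, 454, 466, 709 or 588, and the 8 genes given here kept their calls in each.

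Genes of the contractile apparatus moved the other way in SMC. Of this list 5 of 24 fell (7 adjusted over the list alone), camera adjusted p = 1.10e-06 (adjusted p = 0.0723 with an estimated correlation). Tagln, coding for the actin-binding protein transgelin, fell from 13640 ± 1469 to 8213 ± 1660 CPM (log2 -0.73 ± 0.16, adjusted p = 0.0260). Tpm2, a tropomyosin, fell 1.65-fold (log2 -0.72 ± 0.14, adjusted p = 0.0153) and Myl9, the regulatory myosin light chain, 1.71-fold (log2 -0.78 ± 0.16, adjusted p = 0.0211). Myh11, smooth muscle myosin heavy chain (log2 -0.34 ± 0.17, adjusted p = 0.253), and Acta2, smooth muscle actin (log2 -0.64 ± 0.21, adjusted p = 0.103), did not pass, though Acta2 did in DESeq2 (range of adjusted p over alternatives 0.0174 to 0.288). Among the larger falls were Tcap, a sarcomere cap protein (log2 -1.58 ± 0.39, adjusted p = 0.0467), Mfap4, a microfibril protein (log2 -1.15 ± 0.23, adjusted p = 0.0202), and Carmn, a non-coding RNA of smooth muscle (log2 -0.96 ± 0.20, adjusted p = 0.0228). The retinol carrier Rbp4 (log2 -0.99 ± 0.087, adjusted p = 0.000901) and the proteoglycan Optc (log2 -1.04 ± 0.13, adjusted p = 0.00261) fell too. Smim5, Inka2 and Cidea also fell (log2 -1.40, -0.93 and -0.87). Tagln, Tpm2 and Myl9 were called in none of the fits without WT 1, WT 2, WT 3, WT_VD 2 or WT_VD 3, where the highest adjusted p of a named gene was 0.152, 0.148, 0.141, 0.172 and 0.136. Mfap4 was lost there and without WT_VD 1 (0.0877), and Tcap, Carmn and Inka2 without WT 2, WT 3 or WT_VD 3 (Tcap also without WT_VD 2 and Carmn without WT 1). The SMC came from unlike clusters. Of WT cells 8377 lay in cluster 0, of WT_VD cells 2392 in cluster 0 and 1634 in cluster 7, and of KO_VD cells 854 in cluster 7. Cluster 12, led by Spp1, Vcam1 and Timp1, held 108, 921 and 449 SMC of WT, WT_VD and KO_VD.

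**Figure D2:**
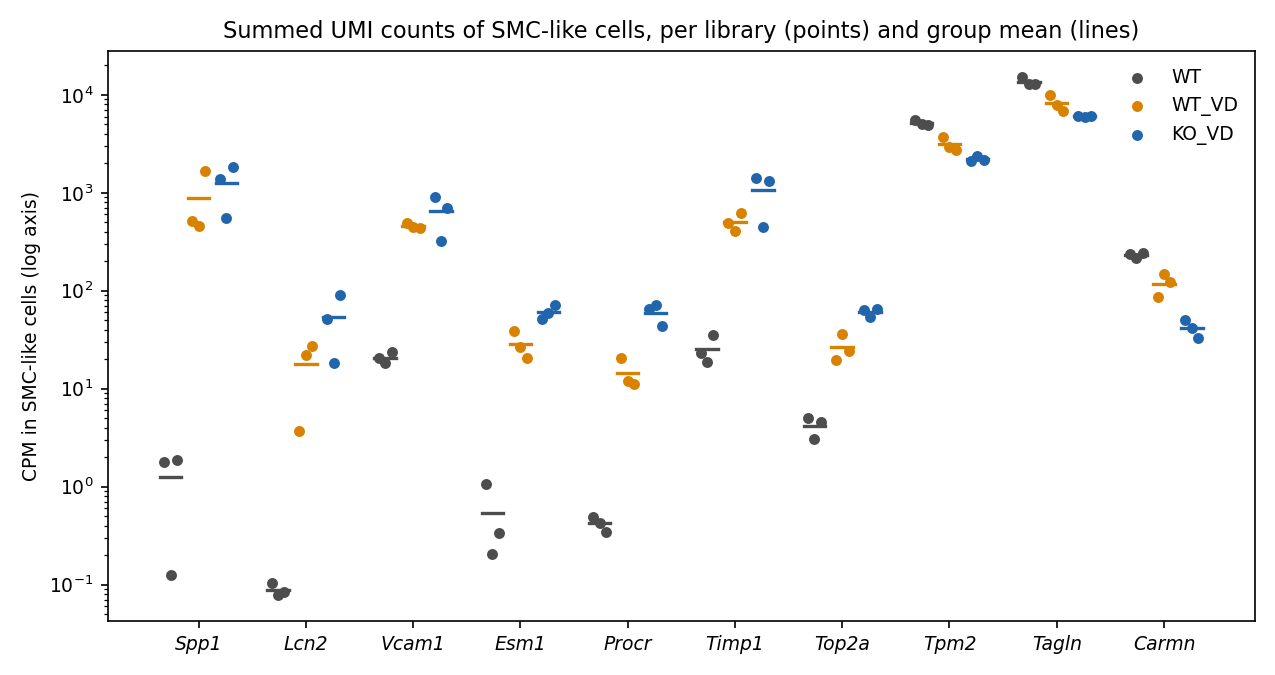
CPM of 10 genes in SMC (log axis) for each library (points), with group means (lines), in WT, WT_VD and KO_VD. Spp1 and Lcn2 lie higher in every WT_VD library than in every WT library.

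Genes linked to mineral deposition were mixed. Osteochondrogenic genes were not called as a group: 3 of 22 rose (4 adjusted over the list alone), camera adjusted p = 0.652. The 3 were Spp1, the decoy receptor gene Tnfrsf11b (osteoprotegerin; log2 1.86, adjusted p = 0.00195) and the chondrogenic factor Sox9 (log2 1.11, adjusted p = 0.0379). The osteogenic factor Runx2 gave log2 1.12, adjusted p = 0.0597 and the phosphatase gene Alpl log2 0.12, adjusted p = 0.814. Runx2 passed in DESeq2, with doublets kept and without WT_VD 1 (range of adjusted p over alternatives 0.00955 to 0.261). Of the list of calcification inhibitors and phosphate handling 6 of 17 rose (8 adjusted over the list alone), camera adjusted p = 3.23e-06. They included Smpd3, a sphingomyelinase needed for bone mineral (log2 2.45 ± 0.19, adjusted p = 0.000744), and Mgp, the matrix Gla inhibitor of calcification (log2 0.97 ± 0.22, adjusted p = 0.0318). The list holds genes that favour mineral and genes that restrain it, so its direction does not show more restraint. Mgp missed the threshold with a replicate block (adjusted p = 0.0513, range over the alternatives 0.000138 to 0.116). Sox9 and Mgp were lost without WT 1, WT 3, WT_VD 1, WT_VD 2 or WT_VD 3 (highest adjusted p of a named gene 0.152, 0.141, 0.0877, 0.172 and 0.136), and Mgp without WT 2 (0.148). Among vitamin D receptor targets 3 of 11 rose (5 adjusted over the list alone), camera adjusted p = 0.000845. Cyp24a1, the catabolic enzyme induced by the receptor, had 1 UMI in SMC of WT_VD 1 and 0 in SMC of the other libraries.

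Matrix and inflammatory groups rose in SMC. Of genes of the fibrillar and elastic matrix 7 of 25 rose (11 adjusted over the list alone), camera adjusted p = 4.14e-13 (adjusted p = 0.103 with an estimated correlation). They included the fibulin Fbln2 (log2 3.22 ± 0.24, adjusted p = 0.000744), the collagen Col12a1 (log2 1.58 ± 0.14, adjusted p = 0.00103) and fibronectin, Fn1 (log2 1.03 ± 0.16, adjusted p = 0.00584). Of matrix proteases and their inhibitors 9 of 23 rose (12 adjusted over the list alone), camera adjusted p = 6.77e-09, with the membrane collagenase Mmp14 at log2 0.99, adjusted p = 0.00398. Of chemokines and cytokines 18 of 22 rose (22 adjusted over the list alone), camera adjusted p = 2.96e-30. Il1b, the cytokine interleukin-1 beta, gave log2 6.16 ± 0.47, adjusted p = 0.000744 and the fractalkine gene Cx3cl1 log2 2.33 ± 0.31, adjusted p = 0.00359. Of NF-kB response genes 8 of 19 rose (11 adjusted over the list alone), camera adjusted p = 5.26e-12 (adjusted p = 0.0628 with an estimated correlation). Among genes marking a modulated SMC state 14 of 18 rose (15 adjusted over the list alone), camera adjusted p = 3.60e-27, with Ly6a, the stem cell antigen Sca-1, at log2 2.20 ± 0.25, adjusted p = 0.00200. Of endothelial activation genes 6 of 15 rose (9 adjusted over the list alone), camera adjusted p = 1.11e-10, and of macrophage activation genes 14 of 20 rose and 0 fell (15 and 1 adjusted over the list alone), camera adjusted p = 8.91e-15. Of MHC class II genes 5 of 9 rose (5 adjusted over the list alone), camera adjusted p = 2.75e-08 (adjusted p = 0.0689 with an estimated correlation). They included Cd74, the invariant chain (log2 4.40 ± 0.54, adjusted p = 0.00287), and H2-Aa (log2 5.29 ± 0.57, adjusted p = 0.00195). Transcripts of immune cells moved in the same sums: 10 of 15 rose (15 adjusted over the list alone), camera adjusted p = 1.25e-17, for example Tyrobp, a myeloid adaptor (log2 3.97 ± 0.40, adjusted p = 0.00123). Cd74 was among the genes used to scale free RNA, so its lost call after subtraction is no independent check. After subtraction of free RNA Cd74 and H2-Aa gave log2 1.11 and 4.59 (adjusted p = 0.750 and 0.164, ranges over the alternatives 4.17e-19 to 0.750 and 4.91e-23 to 0.164). Ly6a and Ccl2 lost their calls there at larger log2, 4.003 and 11.38 (adjusted p = 0.214 and 0.0659, ranges 1.47e-14 to 0.214 and 1.57e-08 to 0.0978). At resolution 2 Ly6a gave log2 0.87 (adjusted p = 0.163).

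Proliferation, sterol and stress genes also rose in SMC. Of cell cycle genes 22 of 24 rose (23 adjusted over the list alone), camera adjusted p = 2.54e-46. They included Top2a, the DNA topoisomerase of dividing cells (log2 2.67 ± 0.25, adjusted p = 0.00106), the cyclin Ccna2 (log2 2.95 ± 0.26, adjusted p = 0.000901) and the kinase Cdk1 (log2 2.44 ± 0.20, adjusted p = 0.000857). Of cholesterol and lipid synthesis genes 10 of 21 rose (13 adjusted over the list alone), camera adjusted p = 6.04e-10. Among them was the synthase gene Hmgcs1 (log2 0.69, adjusted p = 0.00400). Of immediate early genes, which dissociation can also raise, 7 of 22 rose and 0 fell (11 and 1 adjusted over the list alone), camera adjusted p = 5.27e-05 (adjusted p = 0.328 with an estimated correlation). Egr1 gave log2 0.86, adjusted p = 0.0105. Of heat shock genes 6 of 15 rose (7 adjusted over the list alone), camera adjusted p = 2.46e-05 (adjusted p = 0.269 with an estimated correlation), with Hspa1b at log2 1.58, adjusted p = 0.00813. On the senescence list 8 of 17 rose and 0 fell (8 and 1 adjusted over the list alone), camera adjusted p = 0.000108 (adjusted p = 0.0820 with an estimated correlation). On the p53 list 3 of 21 rose (6 adjusted over the list alone), camera adjusted p = 0.00577 (adjusted p = 0.385 with an estimated correlation). Of complement and coagulation genes 5 of 19 rose (9 adjusted over the list alone), camera adjusted p = 0.000166 (adjusted p = 0.110 with an estimated correlation). Of interferon response genes 4 of 20 rose (4 adjusted over the list alone), camera adjusted p = 0.00197 (adjusted p = 0.491 with an estimated correlation), and of MHC class I genes 3 of 13 rose (3 adjusted over the list alone), camera adjusted p = 0.0215 (adjusted p = 0.472 with an estimated correlation). Markers of other wall cells moved with these groups. Of fibroblast transcripts 7 of 15 rose and 0 fell (8 and 1 adjusted over the list alone), camera adjusted p = 7.00e-07 (adjusted p = 0.0645 with an estimated correlation). Of endothelial transcripts 2 of 13 rose (5 adjusted over the list alone), camera adjusted p = 0.0215 (adjusted p = 0.241 with an estimated correlation). Ecscr, an endothelial surface protein, gave log2 1.55, adjusted p = 0.0266, a call lost without any 1 of WT 1, WT 2, WT 3, WT_VD 1, WT_VD 2 or WT_VD 3 (highest adjusted p of a named gene 0.152, 0.148, 0.141, 0.0877, 0.172 and 0.136), as that of Egr1 was without WT 2. Oxidative phosphorylation genes were shifted downward as a list, though 0 of 25 passed singly or over the list alone (camera adjusted p = 7.42e-05, adjusted p = 0.491 with an estimated correlation). Over each library as a whole, the median mitochondrial share of UMIs was 3.45 to 3.88% in WT and 2.16 to 2.43% in WT_VD. In SMC alone it was 4.355 to 4.594% in WT and 3.666 to 3.886% in WT_VD.

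The remaining lists were not called in SMC. Of DNA methylation and demethylation enzymes 2 of 14 rose and 0 fell (2 and 1 adjusted over the list alone), camera adjusted p = 0.667. Uhrf1, a partner of maintenance methylation (log2 3.53 ± 0.39, adjusted p = 0.00194), and the methyltransferase Dnmt1 (log2 0.56 ± 0.14, adjusted p = 0.0465) rose. Dnmt1 was lost with a replicate block (adjusted p = 0.0634, range over the alternatives 0.00646 to 0.172). It was also lost without WT 1, WT 2, WT 3, WT_VD 1, WT_VD 2 or WT_VD 3 (highest adjusted p of a named gene 0.152, 0.148, 0.141, 0.0877, 0.172 and 0.136). Members up and down numbered 4 and 0 of 18 for apoptosis, 5 and 1 of 24 for Wnt and 2 and 0 of 24 for TGF-beta and BMP. They numbered 3 and 0 of 20 for NRF2, 2 and 0 of 17 for the basement membrane and 1 and 2 of 20 for autophagy. For the unfolded protein response and calcium handling 1 of 20 and 1 of 25 rose. None passed among hypoxia (20 measured), Notch (15), erythrocyte (4), other muscle (10) and adipocyte genes (6). Camera adjusted p ran from 0.0685 for the unfolded protein response to 0.667 for the methylation enzymes. In all 24 of the 39 lists were called. Of these 10 held with an estimated correlation. They were calcification inhibitors with phosphate handling, vitamin D targets, proteases, chemokines, cell cycle, lipid synthesis, modulated SMC, endothelial activation, macrophage activation and immune transcripts.

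**Figure D3:**
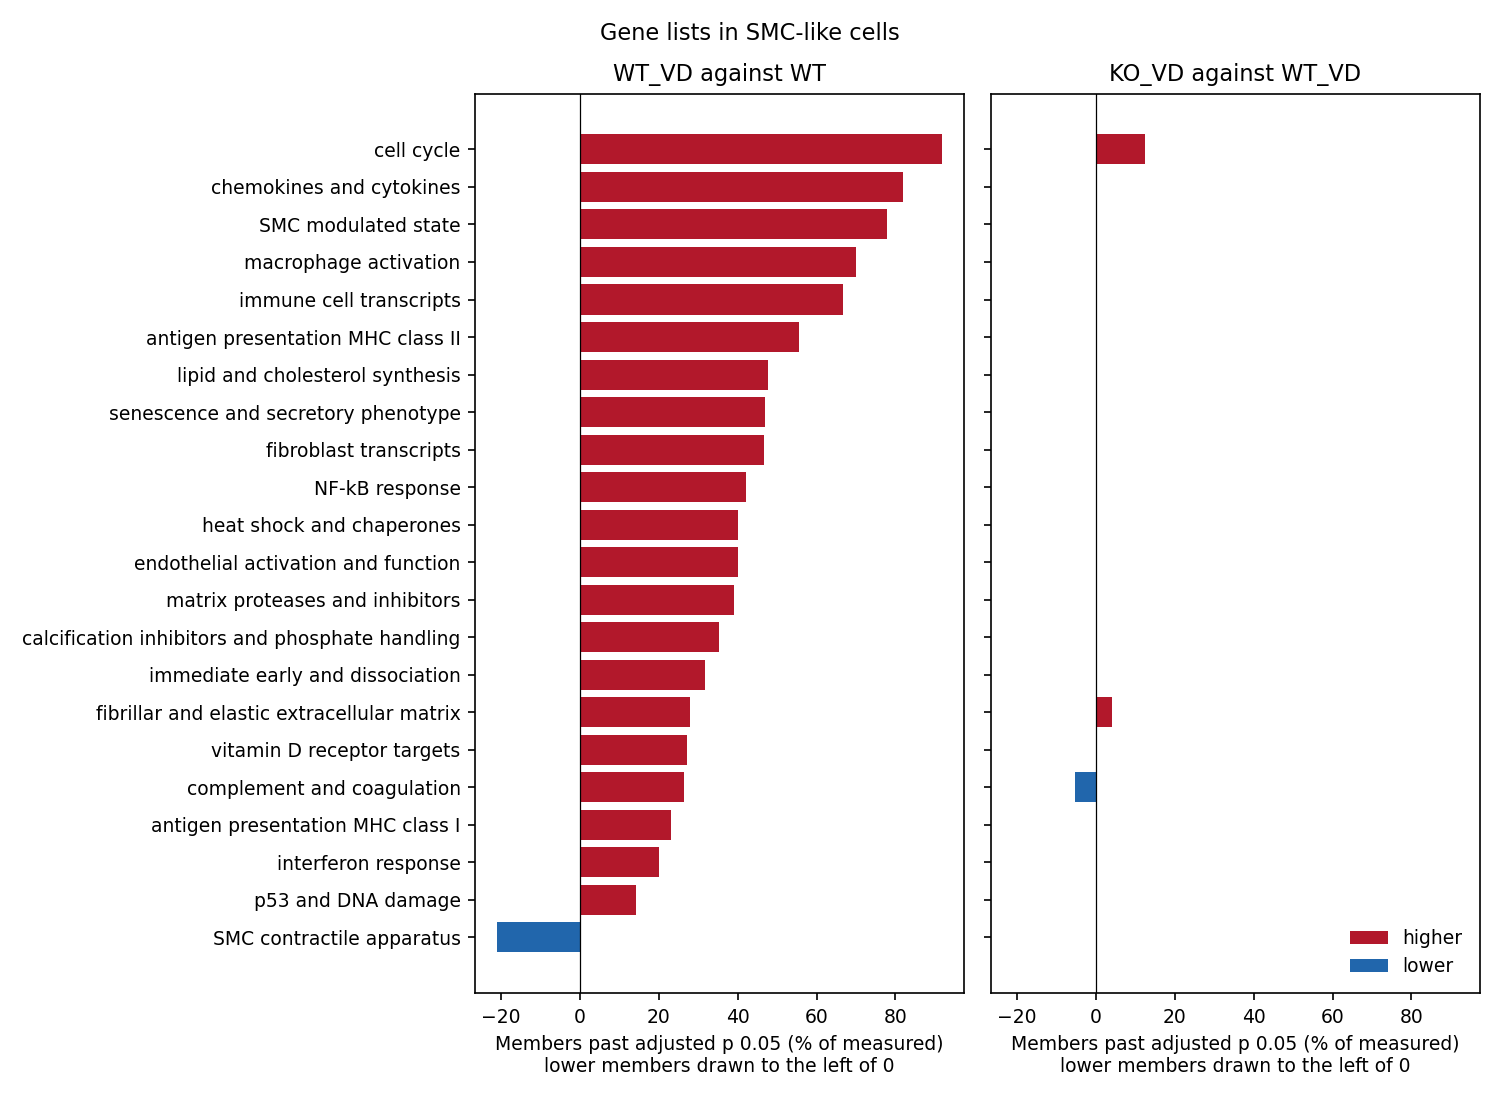
Gene lists in SMC, with the share of measured members past the threshold (%), higher to the right and lower to the left of 0, for WT_VD against WT (left) and KO_VD against WT_VD (right). Both panels draw the same lists, picked as called for WT_VD against WT with several members past the threshold. More of their members pass in the left panel. Lists called only for the genotype are not drawn. Over all lists, drawn or not, 24 were called for WT_VD against WT and 18 for KO_VD against WT_VD.

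The Tet2SMC-KO genotype was then compared with Tet2flox/flox among vitamin D3 treated animals, again in SMC. Procr rose from 14.6 ± 5.23 to 59.7 ± 14.0 CPM (log2 2.02 ± 0.26, adjusted p = 0.0314). With equal cell numbers Procr gave log2 0.33 (adjusted p = 0.838), and in cluster 7 alone 0.75 (adjusted p = 0.631, range over the alternatives 3.05e-10 to 0.838), where Carmn, Pdzrn4 and Col12a1 gave -0.76, -0.55 and 0.30. Hmox1, the heme-degrading oxygenase, rose 3.00-fold (log2 1.58 ± 0.26, adjusted p = 0.0476) and Osmr, the oncostatin M receptor, 1.83-fold (log2 0.87 ± 0.15, adjusted p = 0.0476). The mitotic genes Ube2c (log2 1.50 ± 0.23, adjusted p = 0.0446), Tpx2 (log2 1.40 ± 0.23, adjusted p = 0.0476) and Aurka (log2 1.34 ± 0.19, adjusted p = 0.0400) rose with them. Morrbid, a non-coding RNA of myeloid survival, and AC149090.1, on an unplaced scaffold, also rose (log2 1.44 and 1.67). Dbp, a clock-controlled transcription factor (chromosome 7, 45705088 to 45710203), fell from 116 ± 73.1 to 8.30 ± 4.16 CPM (log2 -3.73 ± 0.63, adjusted p = 0.0476). Tcap fell 6.02-fold (log2 -2.59 ± 0.42, adjusted p = 0.0476), Carmn from 118 ± 31.0 to 41.5 ± 8.44 CPM (log2 -1.51 ± 0.21, adjusted p = 0.0400), and F3, the gene of tissue factor, 5.57-fold (log2 -2.48 ± 0.35, adjusted p = 0.0400). Lamtor3, a scaffold of lysosomal signalling on the Tet2 chromosome (chromosome 3, 137918506 to 137928900), fell from 54.2 ± 10.00 to 19.9 ± 0.898 CPM (log2 -1.44 ± 0.14, adjusted p = 0.0114). Lrrc17, Pdzrn4, Art3 and Stum fell (log2 -1.98, -1.40, -1.06 and -1.06). Of the genes fixed in advance, Myh11 (log2 -0.51, adjusted p = 0.146), Acta2 (log2 -0.16, adjusted p = 0.686) and Spp1 (log2 0.51, adjusted p = 0.706) did not pass, though Myh11 did in DESeq2. Nor did Runx2 (log2 0.86, adjusted p = 0.164), Sox9 (log2 0.55, adjusted p = 0.264) and Alpl (log2 -0.72, adjusted p = 0.180). Of 17059 genes 96 passed, 39 higher and 57 lower (931 with replicates 2 and 3 alone), and the groups did not overlap for 22.8% of all genes against 10% by chance. Without WT_VD 1, WT_VD 2, WT_VD 3, KO_VD 1, KO_VD 2 or KO_VD 3 the genes called numbered 11, 9, 8, 1733, 23 or 3, and of the 20 named genes called 4, 1, 3, 20, 2 or 0 kept their calls. The 6 libraries of both groups alone gave 10, DESeq2 1484, doublets kept 169, equal cell numbers 40 and free RNA subtraction 34. Finer clusters gave 16, cluster 7 alone 8 and cells without Xist 7. With a replicate block 5 of the 20 named genes called kept their calls.

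Gene lists were called in KO_VD SMC with few members past the threshold over all genes. Of cell cycle genes 3 of 24 rose (15 adjusted over the list alone), camera adjusted p = 4.83e-11 (adjusted p = 0.270 with an estimated correlation), with Cdk1 at log2 1.11, adjusted p = 0.0476. Of matrix genes 1 of 25 rose (11 adjusted over the list alone), camera adjusted p = 1.32e-10 (adjusted p = 0.299 with an estimated correlation). The 1 past the threshold was Col12a1 (log2 0.84, adjusted p = 0.0476), with Fbln2 at log2 1.03, adjusted p = 0.0905. Proteases, NF-kB genes, chemokines and unfolded protein response genes were called upward with no member past the threshold over all genes. Adjusted over the list alone 6 of 23 proteases, 9 of 19 NF-kB genes, 4 of 22 chemokines and 12 of 20 unfolded protein genes rose. Their camera adjusted p = 1.70e-06, 6.21e-07, 6.84e-06 and 3.70e-08, and adjusted p = 0.254, 0.299, 0.304 and 0.304 with an estimated correlation. Mmp14 gave log2 0.76, adjusted p = 0.0534, Birc3, an inhibitor of apoptosis, log2 0.89, adjusted p = 0.0507, Ccl2 log2 2.48, adjusted p = 0.103 and Hspa5, the chaperone BiP, log2 1.18, adjusted p = 0.0790. DESeq2 called these 4 and Fbln2. Immediate early and heat shock genes, which dissociation can also raise, were called upward too, with 0 of 22 and 0 of 15 past the threshold over all genes or over the list alone. Their camera adjusted p = 0.00661 and 0.00159, and adjusted p = 0.486 and 0.426 with an estimated correlation. In SMC cluster 7 alone both lists turned direction (camera adjusted p = 0.969 and 0.791). Contractile genes were lower as a list, with 0 of 24 past the threshold singly and 1 up and 10 down adjusted over the list alone. For this list camera adjusted p = 1.17e-05 and adjusted p = 0.270 with an estimated correlation. Of the oxidative stress genes Hmox1 rose and Nqo1, a quinone reductase, fell (log2 -0.92, adjusted p = 0.0400). Immune transcripts were called upward here too, with 0 of 15 past the threshold (camera adjusted p = 0.00159, adjusted p = 0.391 with an estimated correlation). In all 18 lists were called, 11 after free RNA subtraction, 5 with fry and 0 with an estimated correlation. The calls of Hmox1, Cdk1, Col12a1 and Nqo1 were lost without WT_VD 1, WT_VD 2, WT_VD 3, KO_VD 2 or KO_VD 3 (highest adjusted p of a named gene 0.132, 0.151, 0.144, 0.107 and 0.155).

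To ask whether the SMC genes moved by vitamin D3 lay back near the vehicle level in KO_VD, KO_VD was also set directly against WT. In the SMC sums they lay further away. Of the 1053 genes raised in WT_VD 937 were higher still in KO_VD (median log2 0.56 against WT_VD), and of the 229 lowered 211 were lower still (median log2 -0.31). Both comparisons share the WT_VD libraries, which pushes chance agreement the other way: the log2 values correlated at r = 0.461, where simulated libraries without differences averaged r = -0.492. Genes called in both numbered 23 upward and 17 downward, against 2.41 and 0.765 for independent lists. Against WT 6597 genes passed, 3570 higher and 3027 lower (7085 with replicates 2 and 3 alone, 4365 without WT 2). Contractile genes gave 1 up and 15 down of 24 (camera adjusted p = 3.78e-08, adjusted p = 0.0685 with an estimated correlation), cell cycle genes 23 up of 24, modulated SMC genes 16 up of 18 and oxidative phosphorylation genes 12 down of 25. The plot of the SMC genes and the plot of the lists show the steps side by side.

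Fibroblasts, the other abundant wall cell, were asked the same. The comparison was first made for vitamin D3. Saa3, an acute-phase serum amyloid, rose from 0.326 ± 0.194 to 720.1 ± 713 CPM (log2 11.13 ± 1.21, adjusted p = 0.00141). Spp1 rose from 17.5 ± 4.27 to 503 ± 118 CPM (log2 4.84 ± 0.36, adjusted p = 0.000514), the chemokine Cxcl14 101-fold (log2 6.66 ± 0.51, adjusted p = 0.000514), the adhesion molecule Chl1 102-fold (log2 6.67 ± 0.97, adjusted p = 0.00404) and the mitochondrial carrier Slc25a48 130.2-fold (log2 7.02 ± 0.64, adjusted p = 0.000898). Vdr, the vitamin D receptor itself, rose 5.02-fold (log2 2.33 ± 0.29, adjusted p = 0.00205), 1 of the vitamin D targets, of which 5 of 16 rose and 1 fell (6 and 2 adjusted over the list alone), camera adjusted p = 0.00639, adjusted p = 0.162 with an estimated correlation. Omd, coding for osteomodulin, fell (log2 -2.27 ± 0.27, adjusted p = 0.00187), as did the basement membrane collagen Col4a3 (log2 -2.19 ± 0.30, adjusted p = 0.00326). Angptl7, Slc6a7 and the morphogen Bmp4 fell too (log2 -2.66, -2.20 and -1.14). Of 19218 genes 2708 passed, 1659 higher and 1049 lower (3976 with replicates 2 and 3 alone), and 35.8% of all genes did not overlap against 10% by chance. Without WT 2, WT 3 or WT_VD 3 961, 989 or 1031 passed, and Angptl7, Slc6a7 and Bmp4 were lost (highest adjusted p 0.0889, 0.104 and 0.122). Angptl7 and Slc6a7 were lost without WT_VD 1 (0.0650) and Angptl7 and Bmp4 without WT_VD 2 (0.0794). The cells came from cluster 1 in WT (4804 cells) and from clusters 1, 4 and 8 in WT_VD (2562, 1538 and 1428), of which cluster 8 was led by Saa3.

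Of cell cycle genes in fibroblasts 21 of 24 rose (22 adjusted over the list alone), camera adjusted p = 2.14e-49. Mki67 and Plk1, genes of dividing cells, rose by log2 3.62 ± 0.15 and 3.28 ± 0.25. Of matrix genes 12 of 25 rose and 2 fell (15 and 3 adjusted over the list alone), camera adjusted p = 1.04e-05 (adjusted p = 0.280 with an estimated correlation). Tnc, tenascin C, gave log2 3.06, adjusted p = 0.00324 and the collagen gene Col5a2 log2 1.49, adjusted p = 0.00168. Of proteases and inhibitors 10 of 23 rose and 2 fell (10 and 2 adjusted over the list alone), camera adjusted p = 7.79e-07, including Timp1 (log2 3.69, adjusted p = 0.00102) and Mmp19 (log2 1.88, adjusted p = 0.000514). Of chemokines 18 of 23 rose (19 adjusted over the list alone), camera adjusted p = 4.10e-20 (adjusted p = 0.0859 with an estimated correlation), with Il1b at log2 5.87, adjusted p = 0.000669. Of NF-kB genes 8 of 19 rose (12 adjusted over the list alone), camera adjusted p = 1.08e-06 (adjusted p = 0.280 with an estimated correlation). Of sterol and lipid genes 7 of 21 rose (11 adjusted over the list alone), camera adjusted p = 1.49e-05 (adjusted p = 0.267 with an estimated correlation). Sqle, an enzyme of cholesterol synthesis, gave log2 1.71, adjusted p = 0.00706. Among glycolysis and hypoxia genes 8 of 20 rose and 2 fell (10 and 2 adjusted over the list alone), camera adjusted p = 0.00138 (adjusted p = 0.379 with an estimated correlation), with the hexokinase Hk2 at log2 1.82, adjusted p = 0.00138. TGF-beta and BMP genes went lower: 0 of 24 rose and 6 fell (1 and 7 adjusted over the list alone), camera adjusted p = 0.0334 (adjusted p = 0.327 with an estimated correlation), with Tgfbi at log2 -1.42, adjusted p = 0.00181. Transcripts of other cells moved in these sums. Of immune transcripts 11 of 18 rose (15 adjusted over the list alone), camera adjusted p = 4.28e-13 (adjusted p = 0.0859 with an estimated correlation). After free RNA subtraction Tyrobp and Cd74 gave log2 3.11 and 7.14 (4.12 and 5.19 before; adjusted p = 0.358 and 0.377, ranges over the alternatives 4.06e-17 to 0.358 and 2.21e-26 to 0.377). Both were among the genes used to scale free RNA, so their lost calls are no independent check. Of contractile transcripts 2 of 23 rose and 8 fell (2 and 12 adjusted over the list alone), camera adjusted p = 4.78e-05 (adjusted p = 0.162 with an estimated correlation). Myl9 fell by log2 -1.13 ± 0.17 and Cnn1, calponin, by -0.97 ± 0.18, with the sign turned after that subtraction (0.74 and 9.87), and Cnn1 gave -0.23 at resolution 2. Of the 19 lists called, cell cycle, proteases and macrophage activation held with an estimated correlation.

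In fibroblasts of KO_VD, set against WT_VD, Xist stood out, the RNA that coats the inactive X chromosome (X, 103460366 to 103483254), in libraries labelled male. It rose from 0.262 ± 0.135 to 67.2 ± 27.6 CPM (log2 8.04 ± 0.50, adjusted p = 0.00161). Proliferation genes rose further, among them Mki67 (log2 1.18 ± 0.13, adjusted p = 0.0190) and Top2a (log2 1.30 ± 0.24, adjusted p = 0.0342). Of their list 4 of 24 rose (18 adjusted over the list alone), camera adjusted p = 6.23e-15 (adjusted p = 0.133 with an estimated correlation). The prolyl hydroxylase P4ha3, Tex14, Exd2 and the lactate carrier Slc16a3 rose (log2 1.77, 1.83, 1.83 and 1.64). Of fibroblast transcripts 5 of 15 fell (7 adjusted over the list alone), camera adjusted p = 1.33e-06 (adjusted p = 0.187 with an estimated correlation). The proteoglycan gene Dcn fell from 6894 ± 1684 to 3813 ± 503 CPM (log2 -0.86, adjusted p = 0.0467), and gelsolin, Gsn, fell 3.89-fold (log2 -1.96, adjusted p = 0.0340). Dbp fell here as in SMC (log2 -3.59 ± 0.48, adjusted p = 0.0247). Angptl7, Aldh3a1, Fmo2 and Bmp4 fell (log2 -3.28, -2.75, -2.61 and -1.91). Angptl7 and Fmo2 missed the threshold with a replicate block (adjusted p = 0.0514 each, ranges over the alternatives 0.000748 to 0.126 and 9.65e-06 to 0.142). Of the list of calcification inhibitors and phosphate handling 0 of 22 rose and 5 fell (2 and 7 adjusted over the list alone), camera adjusted p = 0.00285 (adjusted p = 0.133 with an estimated correlation). Among those that fell were Gas6 (log2 -1.01, adjusted p = 0.0190), the phosphatase gene Alpl (log2 -1.33, adjusted p = 0.0447) and Bmp4. This list also holds genes that favour mineral, so its direction does not show a loss of restraint. Of complement genes 3 of 19 fell (8 adjusted over the list alone), camera adjusted p = 0.0125 (adjusted p = 0.206 with an estimated correlation). Of immediate early genes 3 of 22 fell (5 adjusted over the list alone), camera adjusted p = 6.83e-05 (adjusted p = 0.379 with an estimated correlation), with Jun at log2 -0.73, adjusted p = 0.0303. Of contractile transcripts 7 of 23 fell (11 adjusted over the list alone), camera adjusted p = 2.02e-08 (adjusted p = 0.133 with an estimated correlation), with Mylk at log2 -1.15, adjusted p = 0.0247. Of 19218 genes 741 passed, 278 higher and 463 lower (2496 with replicates 2 and 3 alone), and 28.6% of all genes did not overlap against 10% by chance. Without WT_VD 1, WT_VD 2, KO_VD 1, KO_VD 2 or KO_VD 3 the numbers were 2, 3, 2246, 29 and 4, and of the 25 named genes called 1, 1, 25, 3 and 1 kept their calls. DESeq2 called 2727, the 6 libraries of both groups alone 1 and cells without Xist 281. The fibroblasts lay in clusters 1, 4 and 8 in WT_VD and mainly in clusters 4 and 8 in KO_VD (2455 and 1536 cells). Of the 14 lists called 0 held with an estimated correlation.

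Whether SMC and fibroblasts answered differently was tested as the difference of their log2 values within each library. With vitamin D3 1985 of 19710 genes differed between the classes, 971 with the SMC value above the fibroblast value and 1014 below (744 with replicates 2 and 3 alone). Vcam1 (log2 4.47 in SMC and 1.38 in fibroblasts), Esm1 (5.75 and 1.67) and Smpd3 (2.45 and -0.75) stood higher in SMC. Mmp14 (0.99 and 2.77) and Cdk1 (2.44 and 4.19) stood higher in fibroblasts. Called in both classes in the same direction were 634 genes. Between KO_VD and WT_VD 141 genes differed, 100 above and 41 below (84 with replicates 2 and 3 alone). Procr (log2 2.02 in SMC and -0.77 in fibroblasts) and Pdzrn4 (-1.40 and 1.27) were among them. After free RNA subtraction most of the 141 calls were lost. With vitamin D3 463, 394, 1280 and 474 genes differed without WT 2, WT 3, WT_VD 1 and WT_VD 3. For the genotype 14, 19, 261, 762, 49 and 16 differed without WT_VD 1, WT_VD 2, WT_VD 3, KO_VD 1, KO_VD 2 and KO_VD 3.

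Endothelial cells were then compared for vitamin D3. The selectins Sele and Selp, which capture leukocytes, rose (log2 2.87 ± 0.53, adjusted p = 0.0321 and log2 1.44 ± 0.28, adjusted p = 0.0328). Of endothelial activation genes 2 of 18 rose and 0 fell (5 and 1 adjusted over the list alone), camera adjusted p = 0.00334 (adjusted p = 0.150 with an estimated correlation). Spp1 had 602 UMIs in WT_VD and 0 in WT, at least 56.8-fold higher by a floor of 3 counts over the group (adjusted p = 0.0328). Of cell cycle genes 16 of 24 rose (23 adjusted over the list alone), camera adjusted p = 1.45e-51 (adjusted p = 0.0638 with an estimated correlation). Mki67 stood at a ratio of 119 (counting interval 32.9 to 985, adjusted p = 0.00624) and Ube2c at 81.2 (27.7 to 394, adjusted p = 0.00497). The aggrecanase Adamts4 stood at 87.2 (15.5 to 3.45e+03, adjusted p = 0.0175). Of chemokines 4 of 17 rose (12 adjusted over the list alone), camera adjusted p = 1.56e-13, the 1 list of 17 called that held with an estimated correlation, with Cxcl2 at log2 5.15, adjusted p = 0.0242. Of matrix genes 2 of 25 rose (11 adjusted over the list alone), camera adjusted p = 1.33e-06 (adjusted p = 0.384 with an estimated correlation), with Col8a1 at log2 2.55, adjusted p = 0.00978. Of basement membrane genes 3 of 17 rose and 0 fell (7 and 5 adjusted over the list alone), camera adjusted p = 0.0121 (adjusted p = 0.384 with an estimated correlation), with Col18a1 at log2 1.76, adjusted p = 0.00497. The protease gene Klk10 (log2 -2.69, adjusted p = 0.0411), the plakin gene Ppl (log2 -2.02, adjusted p = 0.0438), the taurine carrier Slc6a6 (log2 -1.47, adjusted p = 0.00978) and the hydrolase gene Ephx1 (log2 -1.41, adjusted p = 0.0237) fell. Of immune transcripts 2 of 14 rose (10 adjusted over the list alone), camera adjusted p = 2.61e-08 (adjusted p = 0.169 with an estimated correlation). Sele gave log2 1.43 with doublets kept (adjusted p = 0.113, range over the alternatives 2.21e-06 to 0.121) and lost its call with the 6 libraries alone and with equal cells. After free RNA subtraction Spp1 and Cxcl2 gave log2 9.69 and 3.69 (10.71 and 5.15 before; adjusted p = 0.141 and 0.150, ranges over the alternatives 6.44e-08 to 0.141 and 4.75e-07 to 0.150). From 82 to 279 cells per library 279 of 13118 genes passed, 241 higher and 38 lower (630 with replicates 2 and 3 alone, 825 with DESeq2), and 27.3% of all genes did not overlap against 10% by chance. Without WT 1, WT 2, WT 3, WT_VD 1, WT_VD 2 or WT_VD 3 the numbers were 33, 34, 36, 422, 37 and 71, and of the 16 named genes called 4, 5, 4, 15, 4 and 8 kept their calls.

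Between KO_VD and WT_VD endothelial cells 1 gene passed, Mmp13, a collagenase of remodelling matrix, which rose from 1.27 ± 0.394 to 27.8 ± 8.05 CPM (log2 4.41 ± 0.43, adjusted p = 0.0179). It was lost without WT_VD 1, WT_VD 2, WT_VD 3 or KO_VD 3 (adjusted p = 0.176, 0.221, 0.112 and 0.0821). Without KO_VD 1 614 genes and without KO_VD 2 2 genes passed. A replicate block gave 7, replicates 2 and 3 alone 163 and DESeq2 86, with 1279 genes at an unadjusted p under 0.05 in edgeR. MHC class I, MHC class II and interferon genes were lower as lists, with 0 members past the threshold over all genes. Adjusted over the list alone 9 of 13, 6 of 9 and 2 of 21 fell. Their camera adjusted p = 1.12e-08, 4.77e-05 and 2.19e-08, and adjusted p = 0.491, 0.450 and 0.592 with an estimated correlation. Gbp2, an interferon-induced GTPase, gave log2 -3.34, adjusted p = 0.425, and H2-Aa log2 -2.21, adjusted p = 0.425, both called by DESeq2. Of contractile transcripts in the same sums 0 of 22 passed, 4 of them lower adjusted over the list alone (camera adjusted p = 6.36e-07, adjusted p = 0.251 with an estimated correlation). Of proteases 1 of 21 rose (1 adjusted over the list alone), camera adjusted p = 3.89e-05 (adjusted p = 0.251 with an estimated correlation).

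Macrophages were few in WT, so the 3 WT_VD libraries were set against WT 1 and WT 3, with 31 and 26 cells. In macrophages of treated aortas the median over all genes was log2 0.25. Fn1 rose 7.74-fold (log2 2.95 ± 0.32, adjusted p = 0.0106) and Thbs1, thrombospondin, 12.4-fold (log2 3.64 ± 0.66, adjusted p = 0.0353). Of matrix genes 2 of 25 rose (3 adjusted over the list alone), camera adjusted p = 0.000153 (adjusted p = 0.962 with an estimated correlation). Mmp19 and Mmp14 rose (log2 3.52 and 3.33), and of proteases and inhibitors 4 of 22 rose and 0 fell (9 and 2 adjusted over the list alone), camera adjusted p = 0.000949 (adjusted p = 0.715 with an estimated correlation). The glucose carrier Slc2a1 (log2 2.68 ± 0.32, adjusted p = 0.0106) and the hypoxia factor Hif1a (log2 2.04 ± 0.36, adjusted p = 0.0319) rose. Of hypoxia and glycolysis genes 4 of 20 rose (10 adjusted over the list alone), camera adjusted p = 4.27e-08 (adjusted p = 0.139 with an estimated correlation). Of modulated state genes 4 of 18 rose (6 adjusted over the list alone), camera adjusted p = 1.06e-06 (adjusted p = 0.444 with an estimated correlation). Against a floor of 3 counts over the group Saa3, the scavenger receptor gene Olr1, Rhou and B3gnt5 were at least 22.2-fold, 10.9-fold, 10.6-fold and 10-fold higher. Their adjusted p = 0.0459, 0.0137, 0.0119 and 0.0403. With doublets kept Thbs1, Saa3 and B3gnt5 gave log2 2.46, 4.80 and 5.04 and missed the threshold (adjusted p = 0.195, 0.0783 and 0.0507, ranges over the alternatives 2.54e-07 to 0.195, 0.000106 to 0.337 and 0.00195 to 0.177). Thbs1 was also lost without a filter, with the compared libraries alone and with equal cells. Ptchd1, the receptor gene Lilra5, the prostaglandin dehydrogenase Hpgd and the adhesion gene Cadm1 fell (log2 -4.04, -3.86, -3.60 and -3.39). Contractile transcripts were called downward with 0 of 22 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.00344, adjusted p = 0.962 with an estimated correlation). Their median was log2 -0.57 and their mean 0.30. Of 14604 genes 277 passed, 178 higher and 99 lower. Without WT_VD 2 or WT_VD 3 the numbers were 100 and 11, and of the 14 named genes called 13 and 2 kept their calls. With WT 1 or WT 3 left out, or with replicates 2 and 3 alone, a single WT library remains. Whether the calls hold there cannot be told, and the ranges above include such fits.

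Between KO_VD and WT_VD macrophages 0 of 14604 genes passed in edgeR, with 900 at an unadjusted p under 0.05. DESeq2 called 97, a replicate block gave 18 and replicates 2 and 3 alone 7, and without KO_VD 2 1 gene passed. Macrophages of replicates 2 and 3 lay mainly in cluster 3 in both groups. Cluster 17, led by Slc7a11, Il1b and Cxcl3, held 187 WT_VD and 1096 KO_VD cells. Most of them came from replicate 1, with 155 in WT_VD 1 and 860 in KO_VD 1. In those libraries cluster 3 held 134 and 564 macrophages. MHC class II genes, which present antigen, were lower as a list, with 0 of 10 past the threshold and 7 down adjusted over the list alone. For this list camera adjusted p = 1.23e-13 and adjusted p = 0.165 with an estimated correlation. Cd74 gave log2 -1.03, adjusted p = 0.393 and H2-Eb1 log2 -1.21, adjusted p = 0.406. Contractile transcripts were lower in the same sums, 16 of 22 adjusted over the list alone and 0 over all genes, with Myh11 at log2 -1.79, adjusted p = 0.406. For them camera adjusted p = 2.31e-22 and adjusted p = 0.165 with an estimated correlation. Lysosome genes were higher as a list with 1 of 20 up adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.452 with an estimated correlation), and Ctsd, the protease cathepsin D, gave log2 1.02, adjusted p = 0.480. DESeq2 called Cd74, H2-Eb1, Myh11 and Ctsd. Hypoxia and glycolysis genes were higher as a list with 0 members called (camera adjusted p = 0.000170, adjusted p = 0.165 with an estimated correlation). Cell cycle genes were lower with 0 members called (camera adjusted p = 2.60e-08, adjusted p = 0.382 with an estimated correlation).

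How far the answer to vitamin D3 was shared between classes was read from genes called in both. SMC and fibroblasts shared 537 genes called upward, where independent lists would share 93.8, and 97 called downward against 13.5. SMC and endothelial cells shared 146 upward against 15.6, fibroblasts and endothelial cells 147 against 23.2, SMC and macrophages 51 against 11.8, and fibroblasts and macrophages 61 against 17.6. Timp1 was called upward in SMC, fibroblasts and endothelial cells (log2 4.31, 3.69 and 2.76), and Spp1 in the same 3 classes. In endothelial cells neither passed once free RNA was subtracted (adjusted p = 0.0742 and 0.141, range over alternatives 1.17e-08 to 0.0827 and 6.44e-08 to 0.141). Between KO_VD and WT_VD SMC and fibroblasts shared 10 upward and 18 downward, against 0.566 and 1.43. All classes of a library share its dissociation, free RNA and sequencing, so overlap between classes is not an independent repeat.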

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

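The tests of causes in this part, and the splits of the libraries, were chosen only after the results were seen, while the test of the difference between SMC and fibroblasts was planned.

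The SMC share was lower in both vitamin D3 groups. If cells other than fibroblasts merely diluted the SMC, the number of SMC per fibroblast would stay the same. It differed by log2 -1.24 between WT and WT_VD and by log2 -1.48 between WT_VD and KO_VD, without overlap. This argues against dilution by such cells as the whole cause. A gain of fibroblasts would lower the ratio too, and the ratio cannot tell it from a loss of SMC. The many unnamed barcodes of WT_VD 2 do not account for the lower share, since without that library it still differed by log2 -1.09. A loss of SMC in the wall may account for the pattern. So may a gain of fibroblasts, or a change in which cells survive dissociation or keep their contractile markers. These cannot be separated here. Nor was the share computed without the cells with Xist, described next.

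Xist was read in KO_VD libraries labelled male. Of cells with at least 15000 UMIs, 1646 of 8426 in KO_VD held at least 3 Xist UMIs, against 1 of 18128 in WT and WT_VD. Among these deep cells of KO_VD 98.3% of Xist UMIs lay in cells with at least 3. This argues against free RNA spread over all of them, and cells with fewer UMIs were not counted. Libraries wholly from female animals are argued against too. In each KO_VD library 77.5% or more of deep cells held a UMI of Kdm5d, Eif2s3y, Uty or Ddx3y. Of the deep cells with Xist 79.8% held no UMI of these Y genes, against 3.18% of those without, so cells of female animals mixed into the KO_VD libraries are a candidate explanation. Which animals were used was not tested, and the share of deep cells with Xist ran over the KO_VD libraries from 6.68 to 13.4% in SMC, 9.73 to 25.6% in fibroblasts, 13.8 to 33.2% in endothelial cells and 10.3 to 47.7% in macrophages.

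Genes called between KO_VD and WT_VD in both SMC and fibroblasts numbered 28. Of these 4 lay within 20 Mb of Tet2 (14.3%, against 1.11% of 16731 genes, odds ratio 15.2, Fisher exact p = 0.000241): A930005H10Rik, Abcd3, Gbp2b and Lamtor3, at 17.6, 11.7, 9.13 and 4.45 Mb. Sequence linked to the Tet2 locus that came with the knockout line is a candidate explanation for these 4, though both groups carry the floxed allele per the labels, and an effect of the deletion itself was not tested. Acting on the genes beside it, it does not reach the other 24 shared genes, which are not known to lie within 20 Mb (AC149090.1 is on an unplaced scaffold), and effects at a distance were not tested. Cells with Xist are argued against as the source of these changes, since without them the changes kept a median of 0.973 of their size in SMC and 0.977 in fibroblasts, with all 27 genes other than Xist in the same direction, though only 6 stayed called in SMC and 13 in fibroblasts.

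Differences between SMC and fibroblasts were called with vitamin D3 for 17 SMC genes named in the text. SMC minus fibroblast was higher for Spp1 (log2 4.51, adjusted p = 0.00709), Esm1 (4.20, adjusted p = 0.000649), Smpd3 (3.19, adjusted p = 0.00491), Procr (3.15, adjusted p = 0.00512), Vcam1 (3.11, adjusted p = 0.00354) and Fbln2 (2.34, adjusted p = 0.00548). It was higher for Cx3cl1 (2.0), Tnfrsf11b (1.68), Col12a1 (1.65), Hspa1b (1.54), Egr1 (1.26), Sox9 (1.17), Mgp (1.01) and Mfap4 (0.86), the last falling by less in SMC. It was lower for Mmp14 (-1.80), Cdk1 (-1.79) and Alpl (-1.42), with log2 0.12 for Alpl in SMC and 1.62 in fibroblasts. Between KO_VD and WT_VD it was higher for Procr (2.74, adjusted p = 0.0219) and Birc3 (0.95, adjusted p = 0.0373) and lower for Pdzrn4 (-2.66, adjusted p = 0.0242) and Lrrc17 (-2.29, adjusted p = 0.0462).

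Other splits of the same 6 libraries make 10 with the real one, too few for a share under 0.05, and they take no account of the replicate numbers or of replicate 1 standing apart. For vitamin D3 the real split and the highest of the others gave 1282 and 0 genes in SMC, 2708 and 0 in fibroblasts, 279 and 0 in endothelial cells, 24 and 23 lists in SMC, and 1985 and 0 genes for the difference between SMC and fibroblasts. In each of these 1 of the 10 splits gave as many. For the genotype they gave 96 and 2 genes in SMC, 741 and 6 in fibroblasts and 141 and 1 for the difference (1 of 10 in each). They gave 1 and 2 genes in endothelial cells (2 of 10), 0 and 0 in macrophages (10 of 10) and 18 and 24 lists in SMC (2 of 10, the other setting WT_VD 1, WT_VD 2 and KO_VD 2 against the rest). For KO_VD against WT in SMC the numbers were 6597 and 0 (1 of 10).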

How the results depend on the processing

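The settings with free RNA subtraction, without cells with Xist, with replicates 2 and 3 alone, with SMC cluster 7 alone and with shares of named cells alone were chosen after the data were seen. For the genes named in the text 3460 alternative values were computed, of which 2766 kept their direction and side of the threshold, 616 lost the call, 55 gained one and 23 turned sign. Of 723 alternative values for lists 621 held, 99 lost the call and 3 turned direction. Unless a sentence says otherwise the cause was not tested.

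With the replicate number as a replicate block the genes called were 15 between KO_VD and WT_VD in SMC, 7 in endothelial cells and 18 in macrophages, and 529 for vitamin D3 in macrophages. Where the numbers were taken as pairs, the block changed only the calls given in the text and that of Hif1a. Hif1a was lost in fibroblasts for the genotype (log2 0.86). For the genotype in SMC not every correlation of deviations passed 0.1 (0.2, 0.039 and -0.082), so the numbers were not taken as pairs. Nor were they for vitamin D3 in endothelial cells (0.181, 0.129 and -0.018) and, with 2 pairs, in macrophages. DESeq2 called 2602 genes for vitamin D3 in SMC, 825 in endothelial cells and 728 in macrophages, and 1484, 2727, 86 and 97 for the genotype in SMC, fibroblasts, endothelial cells and macrophages. It gave Tet2 in SMC log2 0.002 for the genotype. The stricter filter, which tests fewer genes, called 585 for vitamin D3 in SMC and 3813 for KO_VD against WT, with Tet2 at 0.007 for the genotype. Without a filter the genotype gave 4 genes in endothelial cells and 2 in macrophages, and Tet2 stood at -0.004 for vitamin D3 in SMC. With only the libraries compared, which lowers the residual degrees of freedom, the genotype gave 10 genes in SMC and 1 in fibroblasts, and vitamin D3 425 in endothelial cells and 119 in macrophages.

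Equal cell numbers, which discard counts, left 335 and 40 genes for vitamin D3 and genotype in SMC, 3870 for KO_VD against WT, 62 and 0 in endothelial cells and 86 for vitamin D3 in macrophages, with Tet2 in SMC at -0.10 and 0.13. Free RNA subtraction left 789 and 34 genes in SMC, 11 lists for the genotype and 8 genes for the genotype difference between SMC and fibroblasts. In fibroblasts it turned Myl9 to 0.74 and Cnn1 to 9.87 for vitamin D3 and Tet2 to -0.011 for the genotype, and in SMC it put Tet2 at 0.00 for vitamin D3. An estimated correlation left 10 lists for vitamin D3 and 0 for the genotype, and fry 5 for the genotype. With doublets kept the genotype gave 169 genes in SMC, 0 in endothelial cells and 6 class shares without overlap, with Tet2 at 0.029, and vitamin D3 466 genes in endothelial cells and 175 in macrophages. Leiden at resolution 2 gave 16 genes in SMC and 2 in endothelial cells for the genotype. Among classes also named at resolution 1 it gave 3 and 5 shares without overlap for vitamin D3 and genotype. Classes named only at resolution 2 were not compared. The fibroblast share stood at log2 0.23 for vitamin D3.

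Without cells with Xist the genotype gave 7 genes in SMC, 281 in fibroblasts, 0 in endothelial cells and 88 for the difference, with Tet2 at 0.011 in SMC. Replicates 2 and 3 alone gave 931, 2496, 163 and 7 genes for the genotype in SMC, fibroblasts, endothelial cells and macrophages, 630 for vitamin D3 in endothelial cells and 744 and 84 for the difference. They gave 8 shares without overlap for the genotype, a Schwann cell share of log2 -0.18 for vitamin D3, a fibroblast share of 0.23 for the genotype, Acta2 at 0.068 in SMC and Tet2 at -0.12 in fibroblasts. SMC cluster 7 alone gave 8 genes for the genotype, Tet2 at 0.023 and Acta2 at 0.16, with list adjusted p = 0.882 (osteochondrogenic), 0.969 (immediate early) and 0.791 (heat shock) in the other direction. Shares of named cells alone gave 8 without overlap and a fibroblast share of 0.35 for vitamin D3, and the stricter cell filter a fibroblast share of 0.16 for vitamin D3 and 5 shares without overlap for the genotype. On cell counts edgeR gave vitamin D3 log2 4.73 for macrophages, 4.67 for neutrophils and -0.12 for cartilage cells, and with a replicate block 4.41, 4.77 and -0.25.

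Leaving out single libraries moved the genes called for vitamin D3 between 454 and 1435 in SMC, 961 and 2687 in fibroblasts and 33 and 422 in endothelial cells. In macrophages, with both WT libraries kept, it moved them between 11 and 294. For the genotype they ranged from 3 to 1733 in SMC, 2 to 2246 in fibroblasts, 0 to 614 in endothelial cells and 0 to 1 in macrophages, and for KO_VD against WT from 4365 to 7920. The difference ranged from 394 to 1432 and from 14 to 762 genes, and shares without overlap from 3 to 8 for the genotype. Shares not called for vitamin D3 ranged from log2 -0.39 to 0.47 for adipocytes, -0.50 to 0.49 for cartilage cells and -0.33 to 0.11 for fibroblasts. For the genotype they ranged from -0.30 to 0.14 for fibroblasts and -0.35 to 1.30 for pericytes. Tet2 ranged from -0.052 to 0.053 for vitamin D3 and from -0.13 to 0.069 for the genotype in SMC and from -0.18 to 0.18 for the genotype in fibroblasts, and Alpl in SMC for vitamin D3 from -0.08 to 0.33. Macrophages of WT numbered 31 and 26 in the 2 libraries used, and a 2-fold change simulated in that comparison was recovered for 0% of genes.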

Other observations

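The values in this part were picked only after the data were seen, and no hypothesis was tested here.

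Several clusters without a name were rare in WT. Cluster 9, with Ccr7, Cd86 and H2-Eb1 among its leading genes, as in dendritic cells, made up 0.0566 ± 0.0119% of cells in WT, 5.36 ± 4.54% in WT_VD and 8.73 ± 2.77% in KO_VD. Cluster 13, with Ccl5, Themis and Gzma, genes of T and NK cells, made up 0.734 ± 0.536%, 1.65 ± 0.603% and 4.85 ± 0.162%. Cluster 29 carried Acp5, Ctsk, Mmp9 and Atp6v0d2, genes known from bone-resorbing osteoclasts, at a median of 41101 UMIs. It held 0 of 21126 cells in WT, which allows up to 0.0142% for counting error alone, with 11 cells in WT_VD (0.0483 ± 0.0546%) and 121 in KO_VD (0.638 ± 0.537%, from 0.0283 to 1.04% between libraries). Cluster 15 held 0, 460 and 786 cells at a median of 1066 UMIs, with the fibroblast transcripts Dcn in 84.4% and Sfrp4 in 66.1% of cells and Igkc in 39.9%. Cluster 2 made up 39.3% of WT_VD 2, and 4197 of the 4795 kept cells in cluster 2 came from that library.

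Other clock genes, with no list fixed for them, were read beside Dbp between KO_VD and WT_VD. In fibroblasts Tef and Per3, like Dbp outputs of the circadian clock, gave log2 -1.68 (adjusted p = 0.0249) and -2.35 (adjusted p = 0.0247). In SMC they gave log2 -1.84 (adjusted p = 0.0695) and -2.48 (adjusted p = 0.0799), while Arntl and Npas2, activators of the clock, gave 2.06 (adjusted p = 0.167) and 1.88 (adjusted p = 0.0695). Nr1d1 gave -0.30 (adjusted p = 0.731) in SMC and -0.89 (adjusted p = 0.266) in fibroblasts, and Ciart -0.99 (adjusted p = 0.387) and -0.998 (adjusted p = 0.175). The time of day at collection is not in the labels.

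Gbp2b, a guanylate-binding protein gene on the Tet2 chromosome (chromosome 3, 142594847 to 142619179), gave 25.3, 10.5 and 15.6 CPM in SMC of KO_VD 1 to 3 and at most 0.0467 CPM in SMC of the other libraries. Cmss1 differed between replicate 1 and replicates 2 and 3 by log2 -1.72 ± 0.15 in SMC (adjusted p = 0.0170) and -1.74 ± 0.18 in fibroblasts (adjusted p = 0.0167).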
